A study of Homo sapiens with 4 samples.

How the data were processed

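The series measured ribosome-protected fragments in HEK-293 cells with RiboLace (2 libraries) and standard ribosome profiling (2 libraries), and the labels number them as biological replicates. Per the labels' protocols, cells were held in cycloheximide at 10 µg/mL for 5 min, lysates were digested with RNase I for 45 min, and fragments of 25 to 35 nt were selected. Per the labels' protocols, RiboLace libraries were made from ribosomes captured on beads after digestion. The protocol text given for the standard libraries breaks off after saying that they were handled like the RiboLace ones, so steps that differed are not given in the sources used here.

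The deposited table holds raw counts per Ensembl transcript for the 4 libraries, with the lengths of the transcript and its 5' UTR, coding sequence and 3' UTR in nucleotides. Trimmomatic 0.36, Bowtie2 2.2.6, SAMtools and the genome build GRCh38.p7 are named in the submitters' processing notes, with no role or order. The annotation release, the counting rule, the handling of reads that fit several places and any removal of rRNA reads are not given in the sources used here. The table has 196147 transcripts of 56269 genes, of which 56450 transcripts had 0 counts in every library. Gene symbols were taken from the transcript names in the table. Counts are given over whole transcripts, so reads in coding sequences could not be separated from reads in UTRs. Among 8 U1 genes of identical length, counts were spread evenly in each library (chi-square tests of the counts; 27567 to 27881 in RiboLace replicate 1), as for reads placed at random on one of several equal copies. Counts of a gene were therefore summed over its transcripts without double counting, and genes and transcripts with near-identical copies are uncertain.

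Totals ran from 2615308 to 5900875 counts per library, and the 20 most abundant genes took 26.76%, 31.87%, 29.24% and 28.02% of them (RiboLace replicates 1 and 2, standard replicates 1 and 2). Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, with DESeq2 1.42.0 as an alternative, and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1. Genes were kept by edgeR's filterByExpr, which left 14907. Library sizes were scaled by trimmed mean of M values (TMM, factors 1.037, 0.836, 1.061 and 1.087 in the order above). Genes were tested by edgeR's quasi-likelihood F-test without a block, on all 4 libraries, and adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The common biological coefficient of variation was 0.273. The plan did not say which of edgeR's 2 quasi-likelihood methods to use. The default of the installed version was taken, and the bias-adjusted method became an alternative. The counts from both, 37 and 20 genes, had been seen when this was settled.

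CPM values use the TMM-scaled sizes, except for shares (over the deposited counts of all genes) and agreement (over the counts of the tested genes). Fold changes are fitted values and depend on a small prior count for genes near 0. The ratio for C1QL2 is of scaled counts, with an exact (Clopper-Pearson) interval at 95%.

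Before the data were examined, 24 gene lists were fixed (753 symbols in all), together with the tests, the alternatives and the rule for named genes. Of the symbols, 665 were in the table as written, 86 under an older symbol found through a RefSeq gene table of GRCh38.p14, and 2 were not matched. No coordinates of that table were used, since the builds differ. The 23 lists with at least 5 tested members were tested by camera on limma-voom values with a preset correlation of 0.01, and again with an estimated correlation and by fry. Lists were also set against 10000 random lists of the same size matched on mean expression, as an alternative added after the data were examined.

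Genes were named by this rule: the 10 largest log2 fold changes in each direction past the threshold with a mean log2 CPM of at least 4 and both RiboLace libraries on the same side of both standard libraries, filled with genes of lowest p below the threshold where fewer than 10 passed; per list, the 2 members of largest change past the threshold or else the 2 of highest mean CPM; and the 5 genes of highest mean CPM in each method. A gene that the rule takes but that is withheld from this text is not named, and no other gene takes its place. Genes named outside it are said to have been chosen after their values were seen.

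Shares of counts were compared by two-sided exact permutation tests over the 6 splits of the libraries, with 95% Wilson intervals per library that cover counting error only. Agreement was measured by Pearson's r and Spearman's rho of log2(CPM + 1), and length by Spearman's rho over nuclear protein-coding genes, with the lengths of the protein-coding transcript of highest count. All 11887 such genes tested had a length. The division of a gene's reads over its transcripts was compared by chi-square on counts pooled per method, for transcripts with at least 10 counts in genes with at least 20 counts per method. Called genes were set against 10000 draws of uncalled genes, each from the 20 nearest in count, and again with the RiboLace reads of called genes thinned until they exceeded the standard reads by the ratio of the methods' totals, the imbalance of other genes. Pooling ignores the spread between replicates, and 17.6% of genes passed 0.05 between the RiboLace replicates and 7.98% between the standard ones.

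The gene test was checked on counts simulated from the libraries' means and sizes for the RiboLace against standard comparison of 14907 genes, 5 times with 200 genes changed. Of genes changed by a fold of 2, 7.19% of raised and 4.46% of lowered ones were called. For a fold of 4 the shares were 75.3% and 66%, and for a fold of 8 95.9% and 95.6%. Of 71165 unchanged genes 84 were called. Beside them stood 163 raised and 152 lowered genes called at a fold of 8, 131 and 101 at 4, and 12 and 7 at 2. False calls thus exceeded the share of 0.05 that the threshold allows. The simulation gave both methods the same spread between libraries. Camera called 10 of 10 lists shifted by -1 and 1 of 105 others, and with an estimated correlation 0 of the 10. The simulated genes varied independently, and the shift was larger than the medians of the lists called lower (-0.09 to -0.33). These rates therefore do not measure how camera performs on those lists. In reads simulated with equal division over transcripts, 4.41% of 10199 genes passed 0.05, and with part of the RiboLace reads moved to 1 transcript 87.0% of 200 did.

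Alternatives covered other scalings (DESeq2's size factors by the RLE method, library size alone, TMM factors from nuclear protein-coding genes), DESeq2 and limma-voom, other filters, a replicate block, each library left out, other ways of counting transcripts and a fold threshold. No genome sequence was used here, so base composition was not examined.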

Results

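Ribosome-protected RNA fragments were counted per transcript in HEK-293 cells, an established human embryonic kidney line, by 2 methods. RiboLace captures active ribosomes on beads after nuclease digestion of the lysate. For standard ribosome profiling the protocol text breaks off, so its own steps are not known here. Each method had 2 biological replicates, so 4 libraries were compared. The RiboLace libraries held 2615308 and 2696136 counts (replicates 1 and 2) and the standard libraries 5900875 and 3520825. Genes that could be tested had a median of 44 and 39 counts in the RiboLace libraries and of 98 and 60 in the standard ones. Differences are given as log2 fold changes of RiboLace over standard with their standard error (SE), and levels as CPM, counts scaled by the size of their library, with the SD over the 2 libraries of a method.

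The question of the series is how the footprints taken with active ribosomes differ from those of standard profiling. Of 14907 genes tested, 37 were higher with RiboLace and 0 lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of the 37 genes, 24 (64.9%) were nuclear protein-coding genes, a class that made up 79.7% of the genes tested. SOX1, a transcription factor of neural progenitors, stood at 48.9 ± 10.2 CPM (SD, n = 2) with RiboLace against 2.57 ± 0.259 CPM with standard profiling, a log2 fold change of 4.22 ± 0.33 (SE, adjusted p = 0.0163). BCL11A, a zinc-finger repressor known for silencing fetal globin, stood at 783 ± 102 CPM against 55.6 ± 24 CPM (log2 fold change 3.82 ± 0.42, adjusted p = 0.0409). RELN, which encodes the secreted matrix protein reelin, differed by a log2 fold change of 4.25 ± 0.54 (adjusted p = 0.0428), and the adhesion molecule gene DSCAM by 4.25 ± 0.57 (adjusted p = 0.0428). RELN had 145 and 421 CPM in RiboLace replicates 1 and 2, and without replicate 2 its log2 fold change was 3.29. That of DSCAM was 3.51 without RiboLace replicate 2, 3.63 without standard replicate 1 and 4.91 without standard replicate 2.

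Further genes of large change were taken from those of the 37 with a mean log2 CPM of at least 4. RNF165, an E3 ubiquitin ligase gene, differed by a log2 fold change of 4.44 ± 0.37 (adjusted p = 0.0205), the guanine nucleotide exchange factor gene RASGEF1C by 3.99 ± 0.46 and TNFAIP2, named for its induction by tumour necrosis factor, by 3.56 ± 0.31. The microRNA gene MIR221 stood at 123 ± 49.0 CPM with RiboLace (log2 fold change 3.77 ± 0.35, adjusted p = 0.0265). The gene listed under the clone name RP11-382A20.3 had the highest RiboLace level of the 37, at 1260 ± 342 CPM (log2 fold change 4.09 ± 0.46). C1QL2, which encodes a secreted C1q-like protein, had 252 counts over both RiboLace libraries and 4 over both standard libraries. Its count ratio of 129 has a 95% counting interval of 49.6 to 476, and its log2 fold change of 6.82 ± 0.74 was 5.82 without RiboLace replicate 1 and 7.41 without replicate 2.

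Among the genes named after their values were seen, the mitochondrial threonine tRNA gene MT-TT had the lowest adjusted p together with SOX1 (0.0163), with a log2 fold change of 3.02 ± 0.23 and 225 ± 9.66 CPM with RiboLace. The small Cajal body RNA SCARNA10 (2.4 ± 0.26), the 5S rRNA gene RNA5S9 (2.99 ± 0.34) and the microRNA genes MIR425 (2.61 ± 0.34) and MIR93 (1.75 ± 0.24) were also among the 37. Further protein-coding genes past the threshold were the homeobox gene NKX2-3 (3.01 ± 0.38), the synaptic gene RIMS4 (2.58 ± 0.34), the potassium channel subunit gene KCNMB4 (2.68 ± 0.35), the kinase gene MAPK9 (1.74 ± 0.23) and ANKRD28 (1.78 ± 0.24). RNA5S9 and the MIR and SCARNA genes are members of families with near-identical copies or overlap host genes, so their counts are uncertain. With a library of either method left out, the test holds no spread of that method. The number of calls varied widely between such fits, and calls gained or lost in them are not weighed here. Fold changes stayed large without standard replicate 1 or 2: SOX1 had 4.31 and 4.11, RNF165 4.00 and 4.87, and BCL11A 3.41 and 4.31. When each gene was counted by its highest-count transcript, 1 gene passed. This setting drops the reads on other transcripts, and SOX1, RNF165 and BCL11A then stood at 4.23, 4.06 and 4.15. With every transcript tested alone, 310 transcripts passed, and each of the 37 genes had such a transcript.

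**Figure D1:**
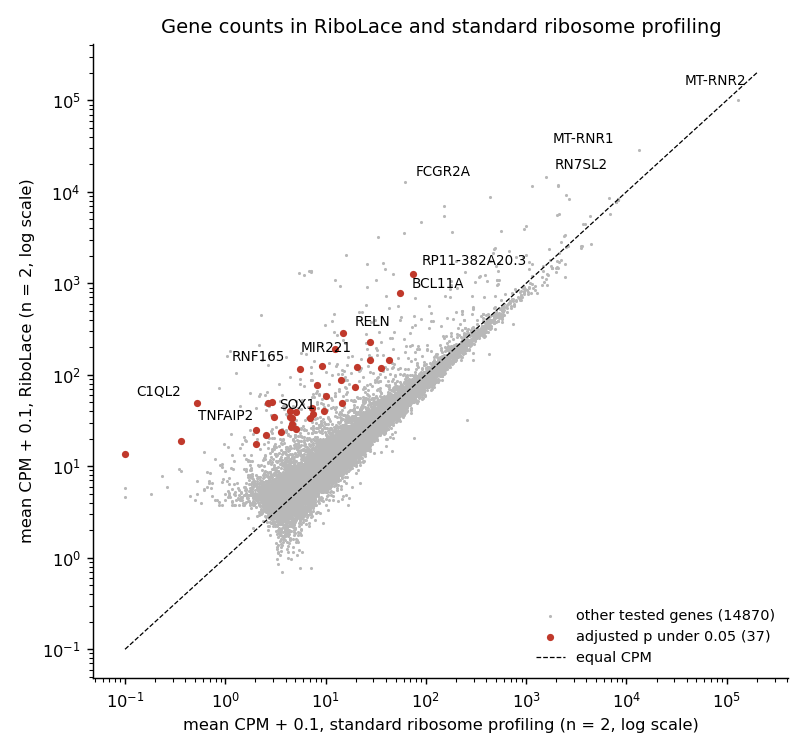
Mean CPM per gene with RiboLace (vertical) against standard profiling (horizontal), both with 0.1 added and on log scales, each the mean of 2 libraries. The 37 genes with an adjusted p under 0.05 (red) lie above the line of equal CPM, and the other tested genes are grey.

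No gene was lower with RiboLace in edgeR's test, although 274 were lower and 1209 higher at an unadjusted p under 0.05. DESeq2 called 2 genes lower and limma-voom 0, and edgeR with no filter on low counts called 47 lower and 896 higher. With library size alone, which moves the median of all genes to -0.20, edgeR called 5 genes lower, with 638 lower and 867 higher at an unadjusted p under 0.05. The 10 lower genes of lowest p with enough counts were all below the threshold, and 5 of them were small guide RNAs of the nucleolus and Cajal bodies. That class was mixed, with 17 genes higher and 23 lower of 132 at an unadjusted p under 0.05. Its summed share was 0.478% and 0.861% in RiboLace replicates 1 and 2, and 0.46% and 0.432% in the standard replicates. The snoRNA SNORD20 stood at a log2 fold change of -1.66 ± 0.25 (adjusted p = 0.0588), the small Cajal body RNAs SCARNA14 and SCARNA18 at -1.93 ± 0.38 and -1.15 ± 0.3, and the snoRNAs SNORA53 and SNORD110 at -1.23 ± 0.26 and -1.03 ± 0.28. Of mRNAs of mitochondrial proteins, MRPL13 (mitochondrial ribosome) stood at -1.01 ± 0.27 and ATP5I (ATP synthase, now ATP5ME) at -0.78 ± 0.21. SNORD20 passed in DESeq2 (-1.66) and in edgeR with library size alone (-1.86), at least 50 counts (-1.59) or no filter (-1.78). It stood at -1.56 and -1.76 with RiboLace replicate 1 or 2 left out. SCARNA14 passed in DESeq2 (-1.92) and in edgeR with library size alone (-2.18) or no filter (-2.06). It stood at -1.42 and -2.68 with RiboLace replicate 1 or 2 left out. With no filter, 7 of the other 8 passed too, but not ATP5I. The pseudogenes SCDP1 (-1.04 ± 0.23) and RNU1-34P (-1.05 ± 0.3) and the clone-named RP4-734P14.4 (-1.03 ± 0.25) made up the rest.

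The mitochondrial rRNAs were the most abundant genes by mean CPM in both methods. MT-RNR2, the large mitochondrial rRNA, took 101000 ± 31600 CPM with RiboLace and 131000 ± 16500 CPM with standard profiling, and MT-RNR1, the small one, 28700 ± 9880 and 13500 ± 2350 CPM. The next genes in the standard libraries were the U1 spliceosomal RNA copies RNU1-27P, RNU1-28P and RNU1-4, at log2 fold changes of -0.02, -0.02 and -0.01. These copies shared reads: 8 genes of identical length held between 27567 and 27881 counts each in RiboLace replicate 1. In RiboLace the next genes were RN7SL2, the RNA of the signal recognition particle (14700 ± 11400 CPM, log2 fold change 3.23 ± 0.79, adjusted p = 0.212), FCGR2A and CTD-2651B20.6. FCGR2A, an Fc receptor gene of blood cells, had 339 and 25500 CPM in RiboLace replicates 1 and 2. All 57326 of its RiboLace counts were on FCGR2A-018, a transcript annotated for nonsense-mediated decay, and FCGR2A-001 and FCGR2A-002, which code for the receptor, had 0. Whether that transcript overlaps a tRNA or other gene could not be examined, so these counts are not read as receptor mRNA. The clone-named CTD-2651B20.6 had 1400 and 22400 CPM. Neither passed (adjusted p = 0.239 and 0.56). Without RiboLace replicate 2 the log2 fold change of CTD-2651B20.6 went from 2.53 to -0.56, that of FCGR2A from 7.71 to 2.48 and that of RN7SL2 from 3.23 to 2.07. Without RiboLace replicate 1 FCGR2A stood at 8.72 and RN7SL2 at 3.86. With a lone RiboLace library such fits hold no spread of that method, so they are not read as calls.

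Gene lists fixed before the data were examined showed no member past the threshold over all genes in any list. Adjusted over the list alone, 1 immediate early gene was higher and no other member passed. By camera with a preset correlation of 0.01, 14 of 23 lists were lower and 2 higher relative to other genes. None of these 16 calls held with an estimated correlation (camera adjusted p = 0.496 for each of the 16 lists). In simulated counts the estimated correlation also called 0 of 10 lists shifted by -1, so it cannot decide these calls either way. Fry, which was not tried on simulated counts, called 0 lists too. All list values below are medians of the members' log2 fold changes. Random lists matched on mean expression to the 14 lower lists also lay below 0, with medians of -0.0762 to -0.146. A value below 0 alone therefore does not set a list apart from other genes of its abundance.

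Nuclear genes of energy metabolism lay below 0 as groups. Random lists matched on mean expression had medians of -0.142 (oxidative phosphorylation), -0.0762 (mitochondrial ribosomal proteins), -0.116 (glycolysis) and -0.0773 (cholesterol synthesis). Of the 70 nuclear-encoded oxidative phosphorylation genes, 66 were below 0 (median -0.25, camera adjusted p = 1.02e-09), among them ATP5B (now ATP5F1B, -0.42 ± 0.33) and ATP5A1 (now ATP5F1A, -0.23 ± 0.28). Of 74 mitochondrial ribosomal protein genes, 57 were below 0 (median -0.19, camera adjusted p = 6.87e-05), with MRPS34 at -0.22 ± 0.32 and MRPL37 at 0.05 ± 0.22. All 18 glycolysis genes were below 0 (median -0.27, camera adjusted p = 8.07e-05), including GAPDH (-0.56 ± 0.37) and ENO1 (-0.28 ± 0.39). The 22 cholesterol synthesis genes had a median of -0.27 (camera adjusted p = 0.00183), with FDPS at -0.33 ± 0.23. In RiboLace replicates 1 and 2 the lists shifted by -0.118 and -0.422 (oxidative phosphorylation), -0.0561 and -0.281 (mitochondrial ribosomal proteins), -0.122 and -0.519 (glycolysis) and -0.139 and -0.229 (cholesterol synthesis). List calls with a library left out are not weighed, here or below, since such fits hold no spread of that method. Without RiboLace replicate 2 the medians weakened to -0.147 (glycolysis) and -0.0774 (mitochondrial ribosomal proteins). With an estimated correlation the adjusted p of these lists was 0.496.

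Lists of the cell cycle and of protein folding and turnover were lower by the same test. The 36 replication-dependent histone genes had a median of -0.33 (camera adjusted p = 4.33e-06), 31 of them below 0, but the most abundant ones were HIST1H1E (now H1-4) at 0.0015 ± 0.46 and HIST1H3B (now H3C2) at -0.28 ± 0.44. The 30 mitosis genes had a median of -0.30 (camera adjusted p = 6.87e-05), with TOP2A at -0.42 ± 0.29 and CENPF at -0.09 ± 0.29, and the 34 DNA replication genes -0.20 (camera adjusted p = 0.000451), with MCM7 at -0.21 ± 0.31 and MCM2 at -0.22 ± 0.3. Of 31 proteasome subunit genes, 28 were below 0 (median -0.27, camera adjusted p = 6.58e-06; PSMB1 -0.25 ± 0.26, PSMB4 -0.42 ± 0.26). The 39 genes of endoplasmic reticulum chaperones and translocon had a median of -0.23 (camera adjusted p = 0.000115), with CANX at 0.02 ± 0.32 and HSP90B1 at -0.22 ± 0.31. Of the 26 cytosolic chaperone genes, 25 were below 0 (median -0.22, camera adjusted p = 0.000909; HSP90AB1 -0.25 ± 0.33, HSP90AA1 -0.07 ± 0.35). The shifts in RiboLace replicates 1 and 2 were -0.101 and -0.618 for histones, -0.0577 and -0.363 for DNA replication and -0.111 and -0.37 for cytosolic chaperones. Without RiboLace replicate 2 the medians of these 3 lists weakened to -0.115, -0.0758 and -0.134. Without standard replicate 1 the medians weakened to -0.0635 for mitosis and -0.174 for the cytosolic chaperones. For each of these lists the adjusted p was 0.496 with an estimated correlation.

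Of the translation machinery, the 79 cytosolic ribosomal protein genes had a median of -0.09 (camera adjusted p = 0.0366), with RPL8 at -0.23 ± 0.33 and RPL13 at -0.13 ± 0.34. Random lists matched on expression had lower medians, -0.146 among all genes and -0.187 among nuclear protein-coding genes. The ribosomal protein genes were therefore not low for their abundance. The 28 initiation factor genes had a median of -0.175 (camera adjusted p = 0.0227; EIF4A1 -0.13 ± 0.33, EIF3C -0.19 ± 0.32) and the 20 cytosolic aminoacyl-tRNA synthetase genes -0.17 (camera adjusted p = 0.0151; IARS -0.31 ± 0.3, YARS -0.01 ± 0.29). Other mRNAs with a 5' terminal oligopyrimidine tract were not called (23 genes, median -0.14, camera adjusted p = 0.263), and EEF2 and EEF1A1 stood at 0.05 ± 0.4 and 0.06 ± 0.37. The 41 genes of long coding sequences had a median of -0.19 (camera adjusted p = 0.000909), with PRKDC at -0.42 ± 0.32 and FASN at -0.07 ± 0.31. Without RiboLace replicate 2 the synthetases stood at a median of -0.0402 and the initiation factors at -0.174. Without standard replicate 1 these lists stood at -0.0728 and -0.132, the ribosomal proteins at -0.0599 and the long coding sequences at -0.0783. The long coding sequences stood at -0.124 without RiboLace replicate 1. The 4 called lists of this paragraph had an adjusted p of 0.496 with an estimated correlation.

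Lists of stress, pausing and secretion were not called. The 10 tested genes with described pausing or frameshifting had a median of 0.15 (camera adjusted p = 0.283). OAZ1 stood at 0.15 ± 0.24 and OAZ2, the antizyme gene read through a frameshift, at 1.64 ± 0.48 (adjusted p = 0.294), with 186 CPM in RiboLace replicate 1 and 59.8 CPM in replicate 2. Its log2 fold change was 0.61 without RiboLace replicate 1 and 2.23 without replicate 2. The integrated stress response list had a median of -0.11 over 20 genes (camera adjusted p = 0.197; PHGDH -0.11 ± 0.35, ASNS -0.3 ± 0.29). Immediate early genes had a median of 0.02 over 15 genes while camera placed them lower (adjusted p = 0.742), with JUN at -0.28 ± 0.25 and MYC at 0.04 ± 0.29. Selenoprotein genes (19, median -0.05, camera adjusted p = 0.189; GPX4 -0.32 ± 0.24, GPX1 -0.2 ± 0.27) and matrix and membrane cargo (31, median -0.07, camera adjusted p = 0.237; APP -0.1 ± 0.32, APLP2 -0.36 ± 0.26) were likewise not called. Of 17 markers of blood, liver and fibroblasts, 1 had enough counts to be tested, and it did not pass (adjusted p = 0.606).

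The 2 lists higher by camera were of mitochondrially encoded and of structured RNAs. The 13 mitochondrially encoded mRNAs had a median of 1.51 (camera adjusted p = 0.0073), but the list's median shift from the standard libraries was -0.41 in RiboLace replicate 1 and 2.37 in replicate 2. MT-CO1 had 142 and 698 CPM in these libraries (log2 fold change 1.37 ± 0.63, adjusted p = 0.547) and MT-ND5 103 and 622 CPM (0.72 ± 0.69, adjusted p = 0.801). Without RiboLace replicate 1 they stood at 2.1 and 1.5, and without replicate 2 at -0.21 and -1.11. The 25 structured RNAs of ribonucleoproteins had a median of 0.66 (camera adjusted p = 0.000909), with shifts of -0.0064 and 1.13 in the RiboLace replicates. Their most abundant members, the U1 copies RNVU1-18 and RNVU1-7, stood at -0.0083 ± 0.63 and -0.006 ± 0.63. With an estimated correlation both lists had an adjusted p of 0.496. The 20 long noncoding RNAs had a median of 0.25 and were not called (camera adjusted p = 0.199), with MALAT1 at 0.56 ± 0.29 and SNHG1 at -0.55 ± 0.27. Without RiboLace replicate 2 the mitochondrially encoded mRNAs turned from higher to lower (median -0.44 in place of 1.51). The structured RNAs then stood at -0.0247 in place of 0.66.

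**Figure D2:**
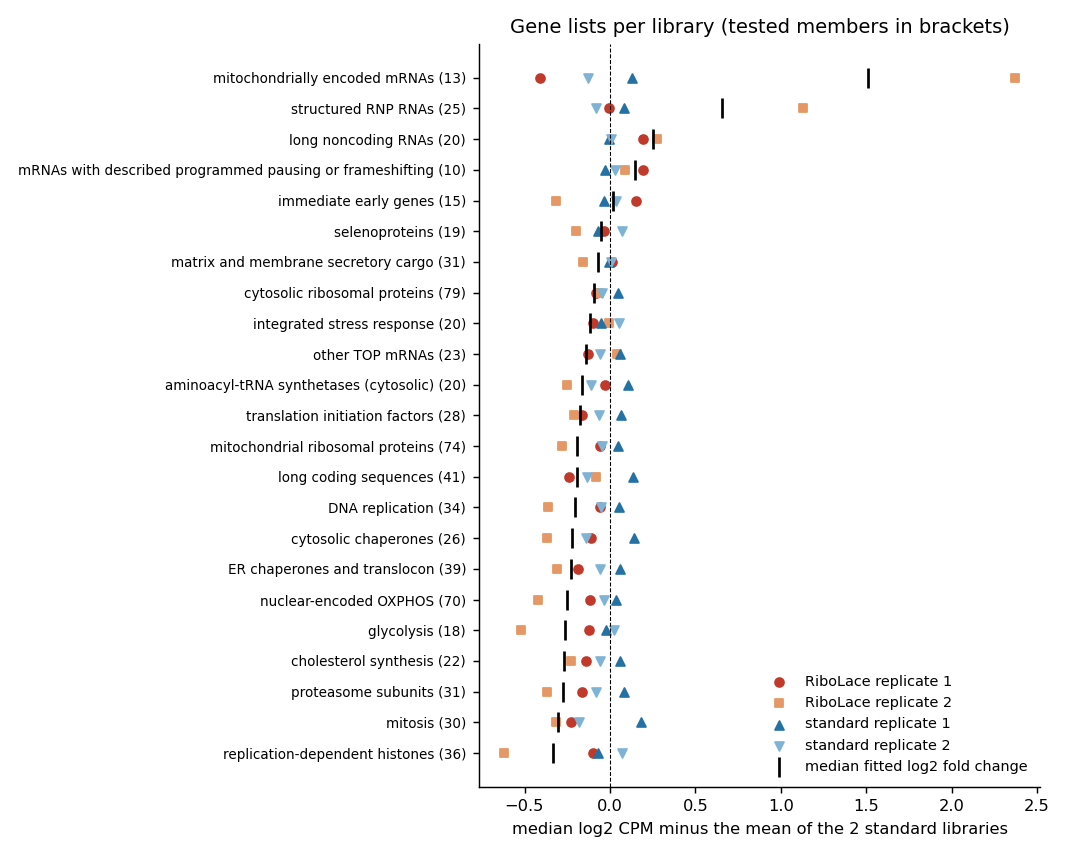
Median log2 CPM of each gene list in each library minus the mean of the 2 standard libraries (horizontal, log2 units), with the median log2 fold change as a black tick. In RiboLace replicate 2 the mitochondrially encoded mRNAs stand at 2.37 and in replicate 1 at -0.41.

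Nuclear protein-coding genes took 53.9% ± 6.34 (SD, n = 2) of counts with RiboLace and 59.7% ± 1.03 with standard profiling. Nuclear noncoding genes took 33.1% ± 3.28 and 24.5% ± 2.76, and mitochondrially encoded genes 12.9% ± 3.06 and 15.8% ± 1.73. The protein-coding share was 58.4% in RiboLace replicate 1 (95% Wilson interval 58.34 to 58.46) and 49.4% in replicate 2 (49.38 to 49.5), against 59.0% (58.93 to 59.0) and 60.4% (60.37 to 60.48) in the standard replicates. Among noncoding classes, 7SL, 7SK, Y and vault RNA genes took 6.99% ± 2.23 with RiboLace and 2.41% ± 0.014 with standard profiling, and mitochondrial tRNA 1.08% ± 0.912 and 0.367% ± 0.0218. Long and other noncoding genes took 9.11% ± 4.0 and 3.8% ± 0.787, while mitochondrial rRNA (11.6% ± 1.96 and 15.3% ± 1.76) and snRNA (13.4% ± 3.56 and 15.3% ± 3.49) were lower on average. For the protein-coding and the noncoding share the 2 methods did not overlap (two-sided exact permutation p = 0.333 for each), and for the mitochondrial share they did (exact permutation p = 0.667). With 2 libraries against 2 the smallest exact p is 0.333, so none could pass 0.05, and the intervals cover counting error only. Without the 20 most abundant genes the mitochondrial difference turned from -2.84 to 1.11 percentage points, and with the highest-count transcript per gene it was -6.5.

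**Figure D3:**
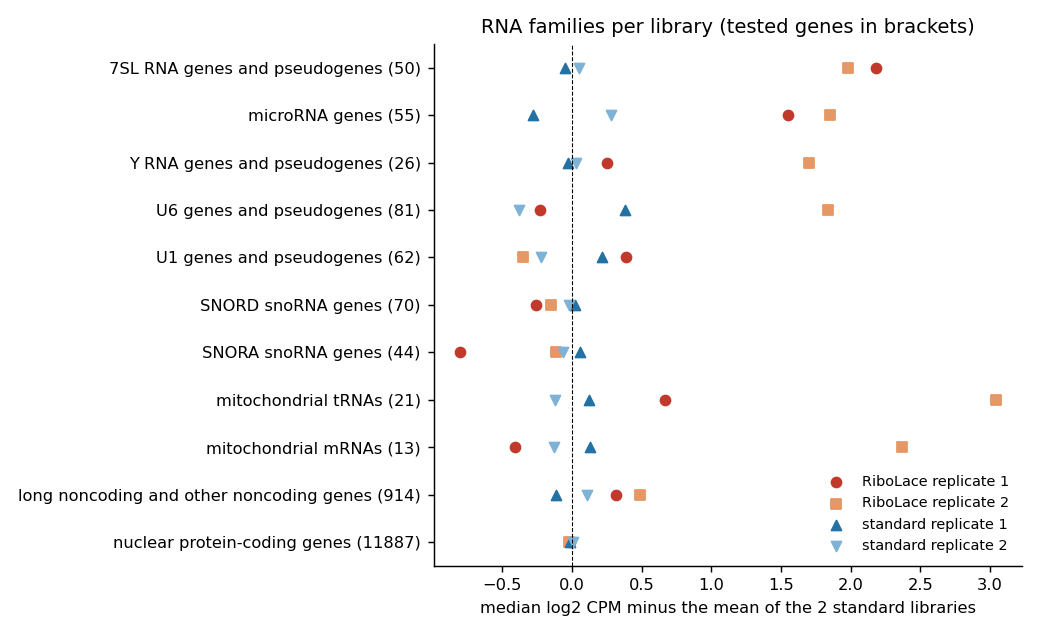
Median log2 CPM of each RNA family in each library minus the mean of the 2 standard libraries (horizontal, log2 units), with the number of tested genes in brackets. The 7SL genes stand at 2.18 and 1.98 in RiboLace replicates 1 and 2, and the mitochondrial tRNA genes at 0.67 and 3.04.

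Agreement of log2(CPM + 1) across the tested genes was lower between the RiboLace replicates than between the standard replicates. Pearson's r was 0.888 (Spearman's rho 0.889) for the RiboLace pair and 0.966 (rho 0.962) for the standard pair. Between methods, RiboLace replicate 1 gave r of 0.912 and 0.927 with standard replicates 1 and 2, and RiboLace replicate 2 gave 0.866 and 0.889. RiboLace replicate 1 was thus closer to both standard libraries than to its own replicate. These correlations run across 14907 genes, which are not independent replicates, and no test was made of them.

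The change with RiboLace had little relation to coding-sequence length. Across 11887 nuclear protein-coding genes, Spearman's rho of the log2 fold change with the coding length was 0.028, and over the 4 pairs of a RiboLace and a standard library it ran from -0.068 to 0.123. The 2378 genes with the shortest coding sequences (711 nt or less) had a median log2 fold change of -0.05, and the 2378 with the longest (2523 nt or more) -0.03. With the whole transcript length rho was 0.201, and with 3' UTR length 0.223. Genes with the shortest 3' UTRs (316 nt or less) had a median of -0.13, and those with the longest (2975 nt or more) 0.14. This relation differed between the RiboLace libraries: rho with 3' UTR length was 0.027 and 0.062 for replicate 1 and 0.274 and 0.313 for replicate 2 against the standard libraries.

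Counts of several genes higher with RiboLace lay on particular transcripts of the gene, examined after the values were seen. In ANKRD28, transcript ANKRD28-003 was 7.93-fold higher with RiboLace (124 ± 36.7 against 15.6 ± 4.91 CPM), while ANKRD28-201 stood at 0.887-fold and ANKRD28-004 at 0.818-fold. In RP11-382A20.3, transcript 001 was 20.2-fold higher (1240 ± 341 against 61.7 ± 31.0 CPM) and transcript 004 stood at 1.42-fold. In MAPK9, the retained-intron transcript MAPK9-010 was 39.9-fold higher (43.7 ± 38.0 against 1.1 ± 0.0514 CPM, 201 against 11 counts). Its counts were 45 and 156 in RiboLace replicates 1 and 2. The coding transcripts of MAPK9 stood at 0.872 to 3.05-fold. In BCL11A, 6 transcripts were 13.2 to 17.4-fold higher, and transcript BCL11A-008, without an annotated coding sequence, stood at 0.578-fold. FMR1, the fragile X gene, did not pass (log2 fold change 2.55 ± 0.36, adjusted p = 0.0515). Its 6 transcripts with annotated 5' UTRs of 217 to 229 nt were 8.29 to 13-fold higher with RiboLace, while FMR1-001, FMR1-002 and FMR1-003, with 5' UTRs of 128 nt, stood at 1.31, 1.57 and 2.45-fold. With every transcript tested alone, ANKRD28-003 (adjusted p = 0.00248), RP11-382A20.3-001 (adjusted p = 0.00528) and MAPK9-010 (adjusted p = 0.00599) passed. The 6 BCL11A transcripts higher with RiboLace passed too (adjusted p = 0.00145 to 0.00234). Several FMR1 transcripts with 5' UTRs of 217 to 229 nt also passed, although the gene did not. Their lowest adjusted p values were 0.00145, 0.00245, 0.00332 and 0.00528. In RiboLace replicate 1 the 6 BCL11A transcripts held 298 to 327 counts each, and the 6 FMR1 transcripts 128 to 154. Such near-equal counts are as for reads placed at random among transcripts that share sequence. These transcripts are therefore not separate evidence, and which of them the reads came from is uncertain.

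**Figure D4:**
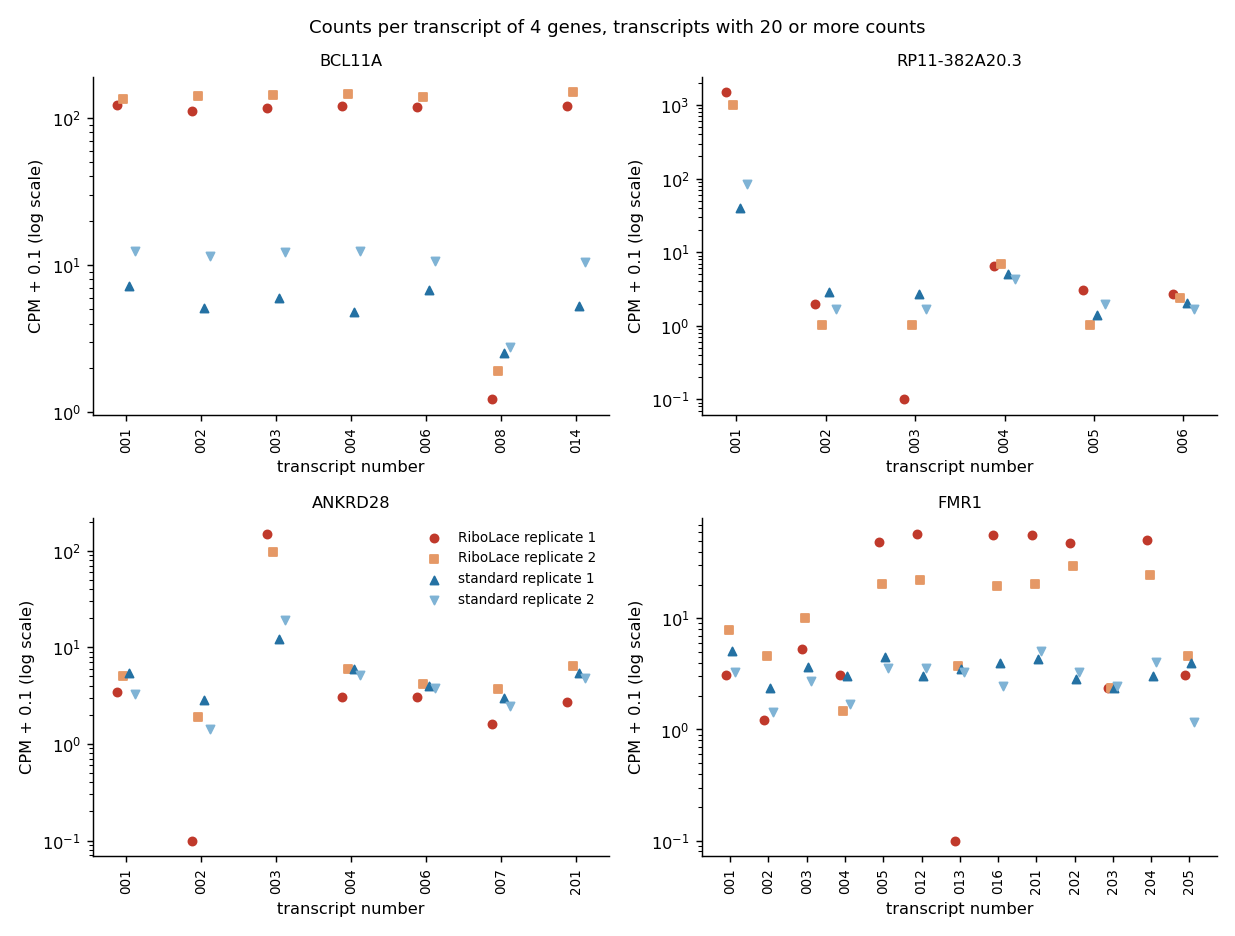
CPM + 0.1 per library (vertical, log scale) for each transcript with 20 or more counts in BCL11A, RP11-382A20.3, ANKRD28 and FMR1, by transcript number (horizontal). Both RiboLace libraries stand above both standard libraries at ANKRD28 transcript 003, 7.93-fold on average, and not at transcript 201.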

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

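Before the data were examined, alternatives were fixed for each result. The bias-adjusted quasi-likelihood test, the TMM factors from nuclear protein-coding genes and the matched random lists were added after the data were examined. Both quasi-likelihood counts, 37 and 20, were known when the default was kept. An alternative on counts per transcript region was not run, since the table has none.

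In place of 37 genes (37 higher, 0 lower), library size alone gave 109 (104 higher, 5 lower; 33 of the 37 shared), with the median of all genes at -0.20 against -0.01. DESeq2 gave 223 (221 and 2; 37 shared), limma-voom 7 (7 shared), the bias-adjusted test 20 (20 shared), no filter 943 (896 and 47; 37 shared), and every transcript tested alone 310 (309 and 1). At least 50 counts per library gave 53 (52 and 1; 32 shared), nuclear protein-coding genes only 148 higher, the highest-count transcript 1 higher, RLE factors 37 and factors from protein-coding genes 47. Leaving out each library gave 0 to 1438 genes (0 to 1336 higher, 0 to 182 lower), where the lone library of a method is assumed to vary like the other group. The replicate block gave 57 genes, 26 of the 37 shared. Replicate numbers need not mark shared cultures: deviations of same-numbered libraries correlated at 0.0775.

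Camera with an estimated correlation and fry gave 0 lists each in place of 16, and leaving out each library 8 to 16. The mitochondrial share moved from -2.84 points to 1.11 without the 20 most abundant genes and to -6.5 with the highest-count transcript. Transcript length gave rho 0.201.

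Values that changed sign follow. Factors from protein-coding genes: RNVU1-7 0.0017. At least 50 counts: YARS 0.06, HSP90AA1 0.00084, FASN 0.0047, RNVU1-18 0.06, RNVU1-7 0.06, RNU1-27P, RNU1-28P and RNU1-4 0.05 each. Highest-count transcript: YARS 0.05, MYC -0.07, OAZ1 -0.09, APP 0.17. Library size: CANX -0.16, MYC -0.12, OAZ1 -0.04, MRPL37 -0.14, EEF2 -0.17, EEF1A1 -0.16, HIST1H1E -0.16. No filter: CANX -0.1, MYC -0.07, MRPL37 -0.06, EEF2 -0.07, EEF1A1 -0.07, HIST1H1E -0.11. HIST1H1E was -0.04 with limma-voom and -0.04 with the block. Immediate early genes had a camera direction that turned, with medians of 0.0992 (at least 50 counts) and 0.0397 (protein-coding genes only).

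Leaving out each library gave these ranges where a sign turned: CANX -0.23 to 0.26, HSP90B1 -0.48 to 0.03, YARS -0.2 to 0.15, HSP90AA1 -0.38 to 0.26, MYC -0.31 to 0.31, PHGDH -0.35 to 0.09, FASN -0.24 to 0.06, APP -0.47 to 0.18, MRPS34 -0.7 to 0.13, MRPL37 -0.03 to 0.11, MT-CO1 -0.21 to 2.1, MT-ND5 -1.11 to 1.5, CENPF -0.43 to 0.27, EEF2 -0.19 to 0.25, EEF1A1 -0.16 to 0.24, HIST1H1E -0.43 to 0.32, GPX1 -0.51 to 0.05, RNVU1-18 -0.45 to 0.35, RNVU1-7 -0.44 to 0.34, EIF4A1 -0.35 to 0.04, CTD-2651B20.6 -0.56 to 3.45, RNU1-27P -0.45 to 0.32, RNU1-28P -0.46 to 0.34, RNU1-4 -0.45 to 0.35. For lists whose direction turned, the medians were -0.312 to 0.218 (immediate early genes), 0.187 to 0.278 (long noncoding RNAs), -0.44 to 2.38 (mitochondrially encoded mRNAs) and 0.0844 to 0.18 (pausing or frameshifting).

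Over all alternatives, values of named genes kept direction and side of the threshold 1201 times, passed it newly 68 times, fell short of it 171 times and turned sign 65 times. For lists these numbers were 212, 1, 53 and 7.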

Other observations

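The family medians, the genes of single libraries and the classes of called genes in this paragraph and the next were examined only after values were seen. For the signal recognition particle RNA, 50 tested RN7SL genes and pseudogenes had a median log2 fold change of 2.47, 43 of them higher at an unadjusted p under 0.05 and 2 past the adjusted threshold. They took 3.8% and 6.49% of counts in the RiboLace replicates and 0.809% and 0.725% in the standard ones, and the median was 2.34 to 2.48 under other scalings. Because 7SL copies share reads, values of single copies are uncertain and not independent, and no test was made of the family. The 55 MIR genes had a median of 1.75 (shifts of 1.55 and 1.85 in RiboLace replicates 1 and 2), with 31 higher at an unadjusted p under 0.05, while their summed share was 0.275% and 0.144% with RiboLace and 0.0506% and 0.133% with standard profiling. MicroRNA genes gave 3 of the 37 called genes from 66 tested (Fisher's exact test, adjusted p = 0.00636). This test takes genes as independent, although copies and host genes can share reads, and it was run on calls already seen. It therefore does not show that the method raises microRNA genes as a class. SNORD and SNORA genes, which guide RNA modification in the nucleolus, had medians of -0.15 and -0.25 and 0 members past the threshold in edgeR as planned, though SNORD20 passed in DESeq2 and under other filters (14 higher and 13 lower, and 0 higher and 7 lower, at an unadjusted p under 0.05). The summed share of SNORD genes was 0.24% and 0.667% with RiboLace and 0.237% and 0.232% with standard profiling. For SNORA genes it was 0.0757% and 0.0849% against 0.114% and 0.0939%.

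Other families differed between the RiboLace replicates, without a test. U6 spliceosomal genes and pseudogenes (81) shifted by -0.23 and 1.84 in RiboLace replicates 1 and 2, Y RNA genes and pseudogenes (26) by 0.25 and 1.7 as medians (their summed share was 1.49% and 1.37% with RiboLace and 1.55% and 1.57% with standard profiling), and 21 mitochondrial tRNA genes by 0.67 and 3.04. U1 genes and pseudogenes (62) went the other way, by 0.39 and -0.35 (12.6% and 5.72% of counts), as did U5 (13), by -0.23 and -0.77. Of genes at least 8-fold above each other library and over 100 CPM, RiboLace replicate 2 had 72, RiboLace replicate 1 had 5 and the standard replicates 0 and 1. The 72 held 11 RN7SL genes, 8 mitochondrial tRNA genes and 23 nuclear protein-coding genes, such as FCGR2A, CTC1 (7110 against 237 CPM in RiboLace replicate 1) and CCND3 (3170 against 127 CPM). Whether their reads come from tRNA or other genes within them could not be examined, and those of FCGR2A lay on a transcript annotated for nonsense-mediated decay. Those of RiboLace replicate 1 included the neural transcription factor gene POU3F1 (708 against 60.7 CPM in replicate 2).

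Both tests in this part were chosen after the 37 genes were seen. Beside 37 genes higher and 0 lower in edgeR, calls stayed mostly higher under each scaling (104 higher and 5 lower with library size, 37 and 0 with RLE factors, 47 and 0 with factors from protein-coding genes), and library size, which moved the median of all genes to -0.20, left SOX1 at 4.05 and BCL11A at 3.6, so library scaling does not account for such folds. Under library size 33 of the 37 (89.2%) were still called, between the bounds set for the test, so its part in the imbalance of the smaller changes is undecided. Excess reads on part of the transcript stay open as a candidate explanation: in 10 of 18 called genes with enough counts (55.6%) the division of reads over transcripts differed between methods, against a median of 16.7% and an upper bound of the central 95% of 33.3% in matched uncalled genes, and in 50% with RiboLace reads thinned. The size of the difference was close, with a median of 12.1% of reads on other transcripts (13.6% thinned) against 11%, the sequence of such segments was not examined, and a biological difference between active and other ribosomes is confounded with the method and was not tested.

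Both tests in this part were chosen after the result was seen. In RiboLace replicate 2, 13 of 13 mitochondrial mRNAs (median log2 ratio 2.57, 0.89 to 3.93) and 21 of 21 mitochondrial tRNAs (median 2.86) were above the mean of the other 3 libraries, though MT-ATP8 (130 and 103 CPM in RiboLace replicates 1 and 2) and MT-TT (219 and 232 CPM) were high in both, and 15 of the 21 tRNAs were above the standard libraries in RiboLace replicate 1 too (family shift 0.67). On more mitochondrial RNA of every kind the rRNAs differed. MT-RNR2, at 0.16, lay below the lowest mRNA by more than its SD over the other libraries (0.44). MT-RNR1, at 1.18, lay within the range of the mRNAs. MT-RNR2 had 78800 and 123000 CPM in RiboLace replicates 1 and 2. The bound on MT-RNR2 alone was worded after an earlier one, which asked for both rRNAs, had decided nothing. Its values were known by then, so this explanation stays undecided. For more RNA fragments from outside coding sequences in that library no test decided: among nuclear genes the ratio of RiboLace replicate 2 over 1 followed 3' UTR length with rho 0.235, but 0 mitochondrial mRNAs have an annotated 3' UTR, so this does not bear on them. With most of it in 1 library, no biological explanation was tested.

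The matched lists were added after the data were examined, with their bounds written before their result was seen. Of the 14 lists lower by camera with a preset correlation, 6 lay within the central 95% of random lists matched on expression, so abundance of the mRNAs may explain DNA replication, aminoacyl-tRNA synthetases, cytosolic chaperones, long coding sequences and initiation factors, while the 6th, cytosolic ribosomal proteins, lay above the range in lists matched among nuclear protein-coding genes (median -0.0913 against -0.187). The other 8 lay below that range: oxidative phosphorylation, mitochondrial ribosomal proteins, proteasome, histones, mitosis, glycolysis, cholesterol synthesis and the endoplasmic reticulum list. Among nuclear protein-coding genes only, 7 did, and glycolysis did not. The random lists were drawn gene by gene, so their range leaves out that members of a list can vary together. It may be too narrow for such lists, so abundance of the mRNAs is not excluded for these 8. None of the 14 was called with an estimated correlation, which called no shifted list in simulated counts either and so decides nothing here. Fry, which was not tried on simulated counts, called none of the 14. A biological explanation is confounded with the method and was not tested.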
